A study of Mus musculus with 14 samples.

How the data were processed

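Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in 7 cell lines grown from mouse small cell lung cancers. Per the labels, suspension cells went through the OMNI-ATAC protocol and paired-end sequencing, and every line had 2 libraries, 14 in all. Per the labels, 3 lines carried the RPR2 genotype and 4 carried RPR2;Nfibf/f, written Nfibf/f below. The RPR2 lines were 12N1G and N2N1G, from lymph node metastases, and 1373M1, from a liver metastasis. The Nfibf/f lines were 1398M1 and 1399M4, from liver metastases, and 1398P2 and 1399P1, from lung tumors. Genotype and tissue were therefore only crossed in liver metastases. The labels do not say whether the 2 libraries of a line came from separate cultures, so the spread between them may be technical. The line was taken as the replicate. Lines 1398M1 and 1398P2 share a number, as do 1399M4 and 1399P1. Whether lines that share a number are independent is not known here, and they were counted as separate lines.

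The deposited files were 1 peak list per library in the narrowPeak layout, not pooled. Per the submitters' processing notes, cutadapt 2.10, Bowtie2, Picard, SAMtools and MACS2 were used and the builds mm10 and GRCm38 were named. Their roles, settings, filters and any shift of reads to the insertion site are not given in the sources used here. All coordinates lay within the GRCm38 chromosomes, and positions are given 1-based on GRCm38. The fold enrichment of each summit, the highest point of a peak, was deposited by the authors as a ratio to the local background of that library. The -log10 p-value and -log10 q-value of each summit were also deposited by the authors, and the lowest -log10 q in every list was 1.3, a q of 0.05. The score that the authors deposited beside each peak was not used. Fold enrichment, p and q were used to rank or filter peaks within a list, and fold enrichment and p also to solve for depth and local background, as described below. The values themselves were not compared between lists, as they are not on a common scale, and background was compared only relative to the floor of its library.

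The lists held no read totals. Under the Poisson model of the peak caller, the fold enrichment and the p-value of a summit together fix its pileup and its local background. This was solved for 1192565 summits with a -log10 p under 250, and 100% of the pileups came out whole within 0.02. The lowest local background of a library, its floor, is the mean number of fragments per base and served as the measure of depth. The floor ranged from 0.507 to 1.134 fragments per bp. Lower depth raises the smallest fold enrichment that can be called, so absence of a peak means absence at the depth of that library. On simulated data the procedure recovered 100% of 4000 pileups and a floor of 0.7.

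Summits of the same peak were merged, and peaks on chromosomes 1 to 19, X and Y were kept. Peaks of all libraries overlapping by at least 1 bp were merged into 177684 regions, of which 119359 were open in at least 1 line. A region was open in a line if both libraries had a peak in it and closed if neither had. A region was specific to a group if it was open in every line of the group and closed in every line compared with it. On simulated lists of 6000 sites this recovered 200 of 200 sites made specific to RPR2 and 100 of 100 made specific to Nfibf/f. Both libraries of a simulated line held all its sites, and no other site was left with a genotype pattern. The simulation therefore checks the counting alone, and not sensitivity or false calls in the real lists.

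Gene positions came from a RefSeq table of GRCm38.p6 that gives the extent of a gene without strand or exons. A promoter was therefore replaced by either end of a gene, within 1 kb, and the nearest TSS by the nearest gene body within 100 kb. No exon, intron or UTR is assigned for the same reason. A protein-coding gene received the regions from 10 kb before to 10 kb past its body. The number of regions per gene and line was the mean of its 2 libraries, scaled by the total of the line over genes, and analysed as log2 of the number plus 0.5. limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend) tested 7070 genes with a mean of at least 3 regions, with Benjamini-Hochberg adjustment at 0.05. A log2 difference on this scale understates the change of genes with few regions. On data simulated for this comparison, with 6364 genes run, 48.9% of the 94 genes changed 2-fold and 98% of the 99 changed 4-fold were called, beside 3 of 6171 unchanged genes. The simulated spread was that of sampling alone, smaller than between these lines, so real sensitivity is lower.

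Differences in means between 3 and 4 lines were tested with a two-sided exact permutation test over all 35 splits, whose smallest p is 0.0286. With 12N1G and N2N1G as 1 line the smallest is 0.067. Counts of specific regions were set beside those of every other split of the same lines. The 4 Nfibf/f lines allow 3 splits into 2 and 2, which cannot reach 0.05. Overlap was the Jaccard index, the shared bp of 2 peak lists over their combined bp. Its difference within minus between genotypes was tested one-sided over the same splits. Gene lists (13 lists, 148 genes, all matched), the tests and the rule for naming genes were fixed before the data were examined, apart from the replacement of promoters and TSSs. The rule takes the targeted genes and the 10 genes per direction with the smallest limma p. It also takes the 10 genes per direction with the most specific regions, or 5 for tissue comparisons, with ties broken by distance. Remaining ties were broken by the alphabet, which was added later. From each list it takes members passing over the list alone, or otherwise the 2 with the largest log2 difference, with only tested genes eligible. List genes with a gene end open in all libraries of 1 genotype and none of the other, and the 3 highest-ranked regions per direction, complete it. Not every gene the rule takes is named in the text. For tissue comparisons and liver lines 1 such region per direction is given. Other genes named below, among them Nfia, Robo1, Esrp2, Hpcal4, the neuroendocrine, hepatocyte and leukocyte genes with gene-end peaks, and those of the other observations, were chosen after their values were seen.

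Alternatives covered the q threshold, equal numbers of peaks per library, region definition and overlap, the open and closed rules, gene windows, filters, scaling, pseudocount, autosomes alone, a replicate block, and leaving out each library, line and replicate number. A further 3 were added after seeing the data: leaving out 1 Mb bins of raised local background, requiring peaks to cover 50% of a region, and counting 12N1G and N2N1G as 1 line. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The planned search for NFI motifs was not run, since no genome sequence was used here.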

Results

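The series profiled accessible chromatin in 7 mouse small cell lung cancer lines, 3 RPR2 and 4 Nfibf/f, with 2 libraries each. RPR2 stands in this field for loss of the tumor suppressors Rb1, Trp53 and Rbl2, and Nfibf/f for a conditional allele of Nfib, which encodes a transcription factor linked to metastasis of this cancer. The title of the series poses the question of which mechanisms of metastasis depend on NFIB. Peaks per library ranged from 65009 to 84220 in 13 libraries and numbered 33558 in replicate 2 of 1398P2. That library also had the lowest background depth, 0.507 fragments per bp, against 0.632 to 1.134 in the others. Open regions per line numbered 57522 in 1373M1, 59286 in 12N1G, 58728 in N2N1G, 58484 in 1398M1, 60336 in 1399M4, 28959 in 1398P2 and 66408 in 1399P1. A total of 17797 regions were open in all 7 lines.

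At the targeted gene Nfib (chromosome 4, 82290173 to 82506751), 25 regions had a peak within the gene or 10 kb around it. The region over the gene end at 82506751, the promoter end of this gene, (82504286 to 82507375) had a peak in all 6 RPR2 and all 8 Nfibf/f libraries. A further 3 regions inside the gene body had a peak in 6 of 6 RPR2 and 0 of 8 Nfibf/f libraries. They lay at 82433971 to 82434302, 82498053 to 82498570 and 82499317 to 82499634. Nfib held 15 regions in 1373M1, 19 in 12N1G and 17.5 in N2N1G, against 9.5 in 1398M1, 10.5 in 1399M4, 6 in 1398P2 and 15 in 1399P1. Its log2 difference of RPR2 minus Nfibf/f was 0.78 ± 0.19 (SE; limma adjusted p = 0.0722 over all genes and 0.00852 adjusted over the list alone). Local background at Nfib was 2.33 to 2.46 times the floor in the 4 lymph node libraries and 1 to 1.32 times in the other 10. The labels do not give the deleted exons, and a peak list does not show where reads are absent, so these values do not test the deletion itself.

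**Figure D1:**
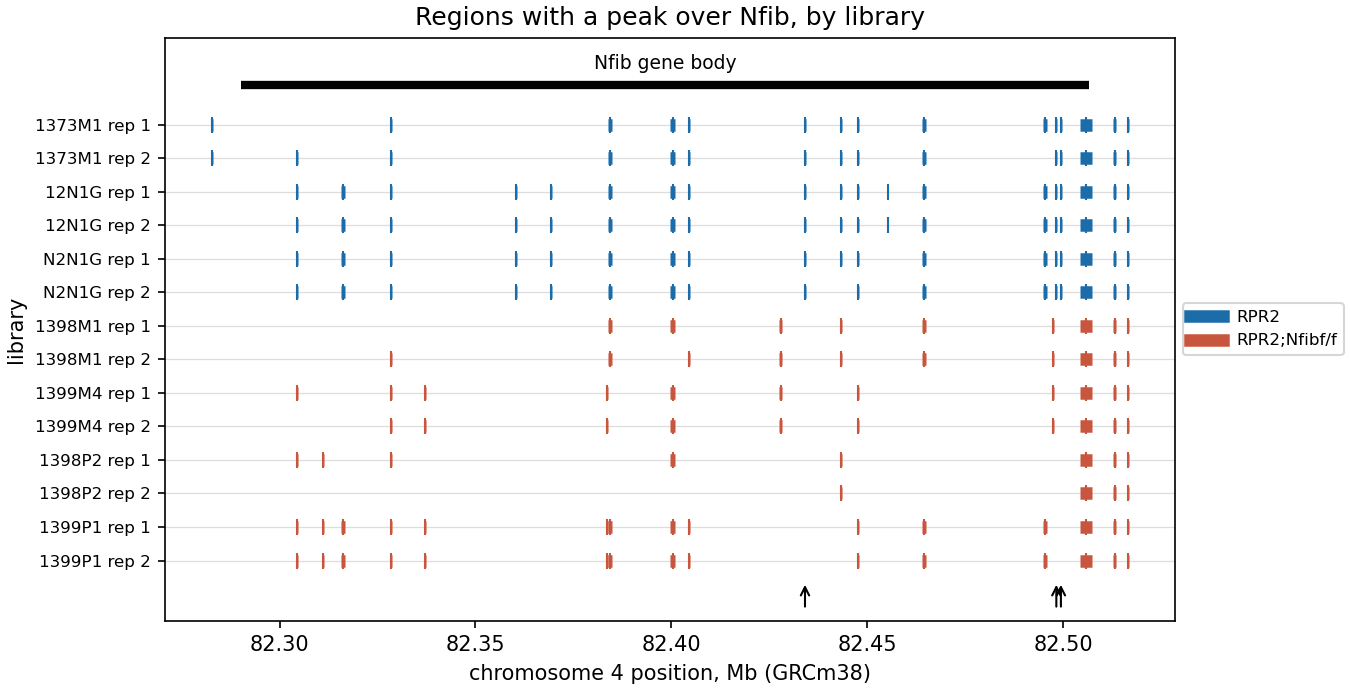
Regions with a peak (marks) along Nfib on chromosome 4 (x axis, Mb, GRCm38) in each of the 14 libraries (y axis), RPR2 in blue and RPR2;Nfibf/f in red, below the gene body (bar). Arrows mark the 3 regions with a peak in 6 of 6 RPR2 and 0 of 8 Nfibf/f libraries.

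The other targeted genes kept peaks at a gene end in all 14 libraries. Trp53 had the same 2 regions in every library, at 69578941 to 69579733 and 69580023 to 69581813 on chromosome 11. In Rb1, 1 region inside the gene (chromosome 14, 73258044 to 73258724) had a peak in 6 of 6 RPR2 and 0 of 8 Nfibf/f libraries. In the other direction, its regions at 73237830 to 73238269 and 73220569 to 73220887 had peaks in 0 of 6 and in 6 and 5 of 8. So did a region beside Rbl2 (chromosome 8, 91060523 to 91061463), in 0 of 6 and 7 of 8. Rbl2 had 2.33 ± 0.58 regions in RPR2 lines (SD, n = 3) and 3.75 ± 0.29 in Nfibf/f lines (SD, n = 4), a log2 difference of -0.6 ± 0.17 (limma adjusted p = 0.0997 over all genes and 0.00954 over the list alone).

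Between genotypes, the genes with more open regions in RPR2 lines included Col13a1, a transmembrane collagen, and Cdh5, the cadherin of endothelial junctions. Col13a1 (chromosome 10, 61838234 to 61979206) had 9.33 ± 0.76 regions in RPR2 lines and 4.25 ± 1.04 in Nfibf/f lines (SD, n = 3 and 4), a log2 difference of 1.08 ± 0.14 (SE; limma adjusted p = 0.0193). Without replicate 1 of 1398P2 it was 1.83 (limma adjusted p = 0.328). Cdh5 (chromosome 8, 104101613 to 104144504) had 5 ± 0.5 against 1.5 ± 0.58 (log2 difference 1.51 ± 0.23, limma adjusted p = 0.0245). Genes with more regions in Nfibf/f lines included Epc2, a member of a histone acetyltransferase complex, Cep170, a centrosomal protein, and Adam10, a membrane protease. Epc2 (chromosome 2, 49450755 to 49551947) had 1 region in each RPR2 line and 4.88 ± 1.25 in Nfibf/f lines (log2 difference -1.81 ± 0.19, limma adjusted p = 0.0125).

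The largest log2 difference among the 10 genes per direction with the smallest p was that of Pabpc4, which encodes a poly(A)-binding protein (chromosome 4, 123282303 to 123298925). It had 9.33 ± 1.76 regions in RPR2 lines and 2.12 ± 0.25 in Nfibf/f lines (log2 difference 1.9 ± 0.16, limma adjusted p = 0.00487). Pabpc4 and Nt5c1a, a cytosolic nucleotidase (1.1 ± 0.17, limma adjusted p = 0.0252), lie beside Mycl on chromosome 4 in bins of raised local background, described below. The RPR2 direction also included Accsl (1.24), Nkd1, an antagonist of WNT signaling (0.91), Rhbdf2 (0.7) and Rasgef1a. In the other direction were Cep170 (-1.31), Gstcd (-1.13), Vwa3a (-1.23), Cdkl3 (-1.32), Wipf1 (-1.27), Slco5a1 (-1.39), Uggt1, a sensor of glycoprotein folding (-1.09), B4galt6 (-1.72) and Adam10 (-1.37). All of these passed a limma adjusted p of 0.05. Of the 20 genes with the smallest p, 10 per direction, Pabpc4 alone kept its call whichever library, line or replicate number was left out, and Epc2 lost it in 2 of 21 such settings that tested it. Leaving out libraries or lines does not separate the call of Pabpc4 from the raised background beside Mycl. Unbroken runs of raised background over Pabpc4 itself lay in RPR2 lines only. They were those of 1373M1 (28.7 and 34.3 times the floor) and N2N1G (39.2 and 35.2 times). In 12N1G the run ended at 122.7 Mb, and in the Nfibf/f lines 1398M1 and 1399M4 at 123.1 Mb, before the gene. Without the 1 Mb bins of raised background 97 of the 100 calls below remained. Pabpc4, Nt5c1a and Hpcal4 were not tested there, with too few or no regions left outside those bins.

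In all, limma called 100 of 7070 genes, 31 with more regions in RPR2 and 69 with more in Nfibf/f, and 1545 genes had an unadjusted p under 0.05. The split of 1399M4, 1398P2 and 1399P1 against the others gave 1289 genes at an unadjusted p under 0.05 and 1 at the adjusted threshold. The count depended on single lines and libraries. It was 2 genes, Pabpc4 and Epc2, with the closely similar lines 12N1G and N2N1G averaged into 1, 2 without line 12N1G, 7 without N2N1G, 6 without 1398P2, 19 without 1399P1, 44 without 1399M4 and 440 without 1373M1. With 12N1G and N2N1G averaged, the log2 differences of the 98 called genes tested were a median of 0.98 times as large, all in the same direction, and their median SE rose from 0.161 to 0.192. Agreement in size and direction is largely built in, since the genes were called on these same lines. Averaging any other pair of a genotype kept all directions as well. Averaging 1373M1 with 12N1G or N2N1G instead raised the median SE to 0.183 or 0.182, yet left 77 and 87 genes. Averaging 1398M1 and 1399P1 left 1 gene at a median SE of 0.165. The number of genes thus did not follow the median SE of the called genes, so these values do not tell what caused the loss. Leaving out single libraries gave 1 gene without replicate 1 of 1398P2, 187 without its replicate 2, 36 without replicate 2 of 12N1G, 32 without replicate 2 of N2N1G and 62 without replicate 2 of 1399M4. With replicate 2 of all lines alone it was 2 and with replicate 1 alone 17. With equal numbers of peaks per library it was 55, of which 6 were among the 100.

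The genes with the most RPR2-specific regions were Grik3, Adamtsl1, Gabbr2 and Magi1. Grik3, a kainate receptor subunit, had 9 such regions, Adamtsl1 7, Gabbr2, a GABA receptor subunit, 5, and Magi1, a scaffold of cell junctions, 5. Auts2, Cdh4, Macrod2, Nfib, Pabpc4 and Sorcs2 had 4 each. No test of enrichment was run on these genes, which are mostly long. Of Nfibf/f-specific regions, 3 lay at Casz1, a zinc finger transcription factor, and 3 at Myo16. Casz1 lies in a bin of raised local background (chromosome 4, 148 to 149 Mb), at 1.85 to 3.98 times the floor in the 8 Nfibf/f libraries and 1.04 to 1.35 times in the 6 RPR2 libraries. The further places went to genes with 2 regions, of which 31 were tied, among them Abca4, Arhgap32, Babam2, Bace2, Bfsp1, Btbd9, Ccdc192 and Ctnnd2.

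The RPR2-specific regions with the highest authors' fold enrichment by rank lay within Rit2 (chromosome 18, 31011793 to 31012135) and Slc24a2 (chromosome 4, 87088624 to 87089193). The third lay 294446 bp from a gene (chromosome 1, 137254894 to 137255500). For Nfibf/f they lay within Dazl (chromosome 17, 50292622 to 50293236), Pde1c (chromosome 6, 56445096 to 56445772) and Nek6 (chromosome 2, 38535973 to 38536938). Their mean rank percentiles within a library were 93.3 to 96.9.

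In total, 1446 regions were RPR2-specific and 763 Nfibf/f-specific, 2209 together, the most of the 35 splits of the lines into 3 and 4 (exact p = 0.0286 for the total). Of these splits, 15 keep the closely similar lines 12N1G and N2N1G together, with 62 to 2209 regions, and the other 20 gave 0 to 33. Among those 15 alone the exact p was 0.067. The RPR2-specific count ranked 1 of 35 by itself and the Nfibf/f-specific count 2 of 35, below 1118 regions closed in 1398M1, 1399M4 and 1398P2 alone. The next split, 12N1G, N2N1G and 1399P1 against the others, gave 1406. Of these, 1399 regions were open in those 3 lines alone, nearly as many as the 1446 of RPR2. Without replicate 2 of 1398P2 the genotype gave 3037 regions and the split of 1399M4, 1398P2 and 1399P1 against the others gave 3042, so the genotype no longer ranked highest, and 1590 of the 3037 were Nfibf/f-specific. The same held without replicate 2 of all lines (5900 against 5984), while the genotype ranked highest in the other 32 of 34 settings. Of the RPR2-specific regions, 3.6% lay within 1 kb of a gene end and 53.7% inside a gene, against 4.7% and 64% of the Nfibf/f-specific regions.

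**Figure D2:**
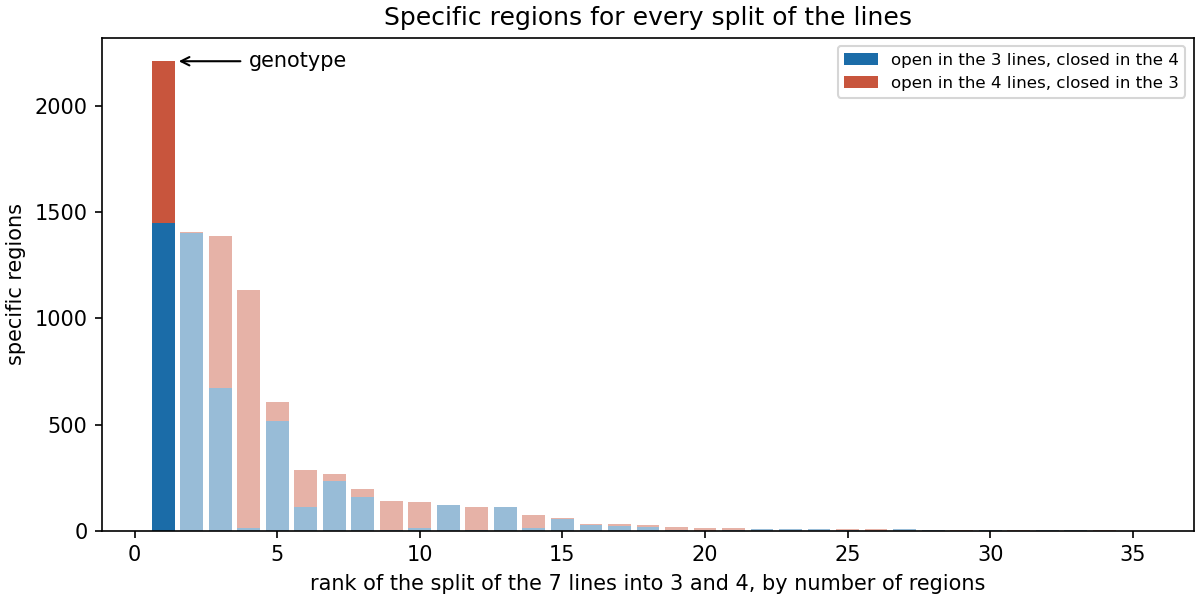
Number of specific regions (y axis) for each of the 35 splits of the 7 lines into 3 and 4 (x axis, ranked), with regions open in the 3 lines alone in blue and in the 4 lines alone in red. The genotype gave 2209 regions and the next split 1406.

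Each gene list was measured as its mean number of regions per gene divided by that of all protein-coding genes of the line, a ratio. Axon and neuron projection genes stood at 3.2 ± 0.26 in RPR2 lines and 2.48 ± 0.33 in Nfibf/f lines (SD, n = 3 and 4; exact p = 0.057, adjusted p = 0.248). Dcx, a microtubule protein of migrating neurons, was higher in RPR2 lines (log2 difference 1.26 ± 0.24, limma adjusted p = 0.00804 over the list alone and 0.0433 over all genes). Slit2, an axon guidance ligand, passed over the list alone (1.04 ± 0.26, limma adjusted p = 0.0227, and 0.0704 over all genes). Of the 18 members tested, 12 had a positive difference and 2 passed over the list alone. With 12N1G and N2N1G as 1 line the difference of Dcx was 1.27 ± 0.28 (limma adjusted p = 0.143 over all genes).

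Markers of fibroblasts and endothelium had 0.94 ± 0.04 in RPR2 lines against 0.69 ± 0.07 (SD, n = 3 and 4; exact p = 0.029, the smallest the design gives, adjusted p = 0.248). Of the 4 members tested, Cdh5 (limma adjusted p = 0.000347) and Pecam1 (log2 difference 0.55 ± 0.18, limma adjusted p = 0.0239), both endothelial adhesion molecules, passed over the list alone. With equal numbers of peaks per library the difference of the list was -0.028. Cdh1, the epithelial cadherin, had 4.5 ± 0.87 regions in RPR2 and 9.12 ± 1.44 in Nfibf/f lines (log2 difference -0.95 ± 0.17, limma adjusted p = 0.00171 over the list alone and 0.0433 over all genes). With the lymph node lines as 1 it was -0.9 ± 0.19 (limma adjusted p = 0.137 over all genes). The list of epithelial-mesenchymal factors had 1.12 ± 0.08 against 1.27 ± 0.11 (exact p = 0.143, adjusted p = 0.371), and Cdh1 was its only member of 5 tested to pass.

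Neuroendocrine genes did not differ detectably, at 1.4 ± 0.03 against 1.33 ± 0.1 (SD, n = 3 and 4; exact p = 0.286, adjusted p = 0.446). None of the 8 members tested passed. Ncam1, a neural adhesion molecule, had a log2 difference of -0.69. Neurogenic factors (Myt1l 0.35, Myt1 -0.14), the tuft-like state (Avil -0.52, Dclk1 0.52), and NOTCH and YAP genes (Hes1 -0.21, Notch3 0.16) differed as lists by 0.23, 0.03 and -0.02. Their exact adjusted p values were at least 0.446. Markers of lung epithelium (Foxa2 0.32, Muc5b 0.29), and of lymphocytes and myeloid cells (Spi1 0.12, Pax5 0.12), differed by 0.03 and -0.05 (both exact adjusted p = 0.446). Hepatocyte markers differed by 0.08 (exact adjusted p = 0.371), and among them Tat, a liver aminotransferase, passed over the list alone (0.61 ± 0.18, limma adjusted p = 0.0277).

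The NFI family stood at 6.48 ± 0.74 times the mean of all genes against 5.36 ± 2.39 times (exact p = 0.486, adjusted p = 0.574). The difference of 1.117 was 2.213 without line 1399P1 (exact p = 0.1), 0.542 without 1399M4 and 0.673 without 1398P2. The MYC family had 1.09 ± 0.03 against 0.79 ± 0.18 (exact p = 0.057, adjusted p = 0.248). The targeted genes had 2.38 ± 0.1 against 2.01 ± 0.27 (exact p = 0.114, adjusted p = 0.371). Nfib was the only one of 4 NFI members to pass over the list alone (limma adjusted p = 0.0114), and Mycl, the only MYC member tested, had a log2 difference of 0.51 (limma adjusted p = 0.078 over the list alone). Nfia, a close relative of Nfib, had 69 regions in 1399P1 and 12.5 to 33.5 in the other lines. The background at Nfia was 13.83 and 18.29 times the floor in the 2 libraries of 1399P1 and at most 1.66 times elsewhere. Mycl, the oncogene of this cancer on the same chromosome, had 4 or 5 regions in each of the 5 metastasis lines, 1.5 in 1398P2 and 3 in 1399P1. Background at Mycl was 20.08 to 43.73 times the floor in the 10 metastasis libraries and 1.22 to 2.51 times in the 4 lung tumor libraries.

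**Figure D3:**
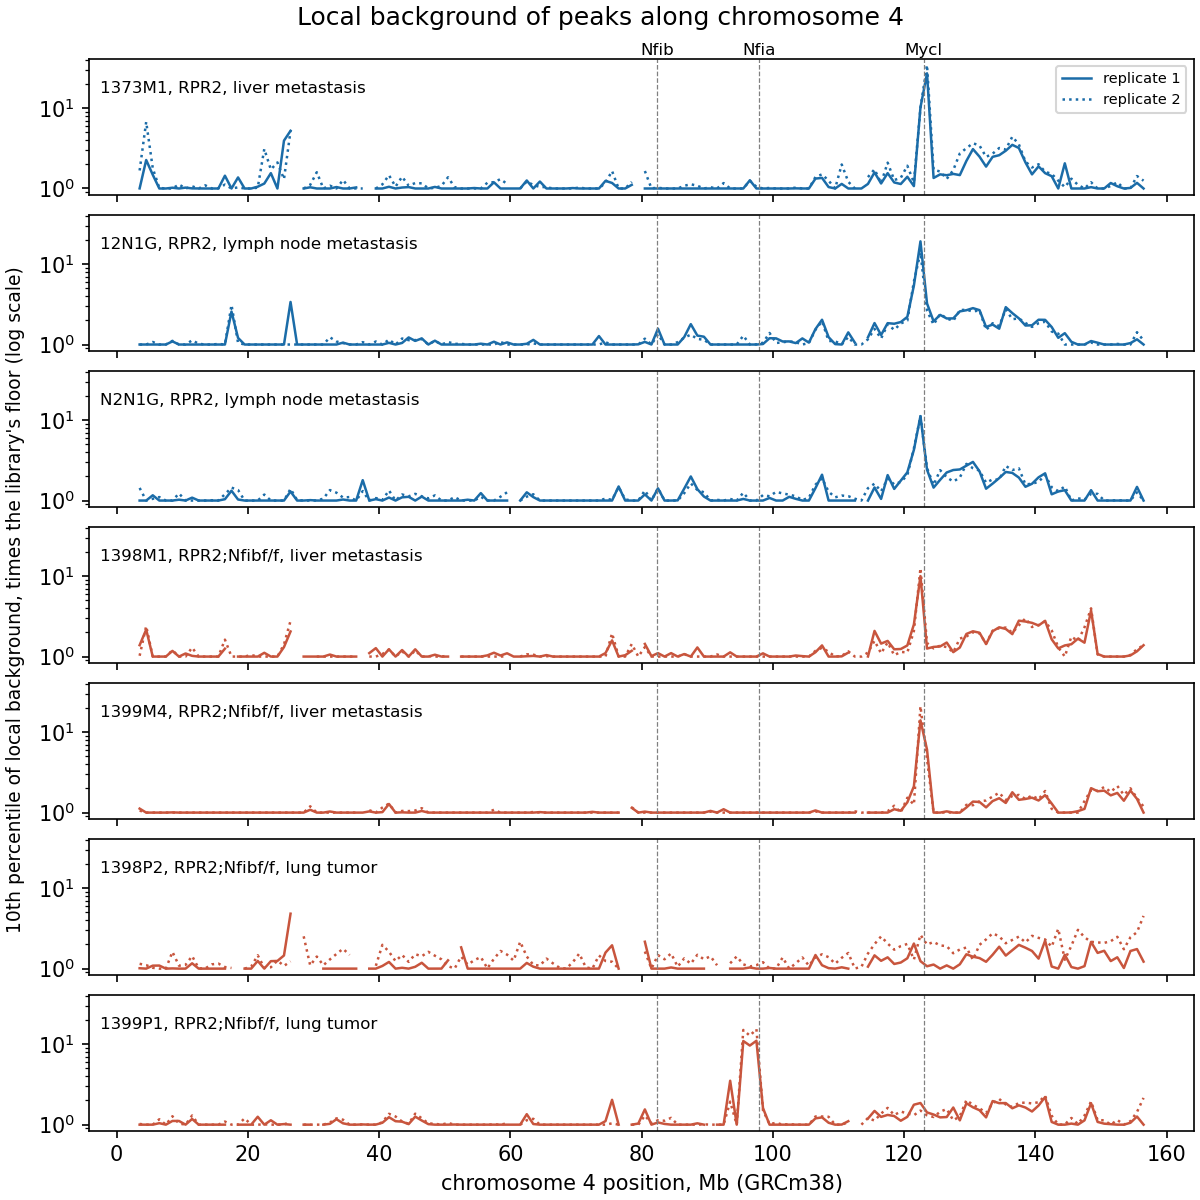
Local background of peaks along chromosome 4 (x axis, Mb, GRCm38) per line, as the 10th percentile in 1 Mb bins relative to the floor of the library (y axis, log scale), with replicate 1 solid and replicate 2 dotted. Gaps are bins without a solved summit, so a drawn value may rest on fewer than 8 summits. The peak at Mycl appears in the 5 metastasis lines and that beside Nfia in 1399P1.

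Of the 148 list genes, 55 had a peak at a gene end in all 7 lines, and 21 had none in any library. Ends of Dcx on the X chromosome were open in 6 of 6 RPR2 and 0 of 8 Nfibf/f libraries (Fisher's exact p = 0.029, adjusted p = 1). Those of Robo1, an axon guidance receptor named after its values were seen, had peaks in 6 of 6 and 1 of 8 (Fisher's exact p = 0.029, adjusted p = 1). In the other direction stood Esrp2, an epithelial splicing factor, with 2 of 6 and 8 of 8 (Fisher's exact p = 0.029, adjusted p = 1). This is the smallest Fisher's exact p of 3 and 4 lines, so 3 genes at it cannot pass adjustment over 148. Insm1, Chga, Chgb, Syp and Dll3 had a peak at a gene end in all 14 libraries, as did 12 of the 16 neuroendocrine genes in all lines. Of the others, Ddc and Scg3 had none in any, yet held 5 to 12 and 2 or 3 regions per library in the gene or within 10 kb. The ends of a gene can miss a promoter inside its extent, so absence there does not mean a closed gene. Among 12 hepatocyte genes, 5 had none in any library, Alb and Afp included, and Apoa1 had one in all lines. Among 12 lymphocyte and myeloid genes, 5 had none, Ptprc included, and Cd4 and Spi1 had one in all lines. Genes with peaks at an end in all libraries of 1 genotype alone numbered 1, Dcx, and 2 without replicate 2 of 1373M1, replicate 1 of 1398M1 or replicate 2 of 1398P2.

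Peak lists of replicates overlapped with a Jaccard index of 0.624 to 0.713 in 6 lines and of 0.25 in 1398P2. The lymph node lines 12N1G and N2N1G overlapped as closely as replicates, at 0.661. Between RPR2 lines the mean was 0.547 ± 0.099 (SD, 3 pairs), between Nfibf/f lines 0.425 ± 0.052 (SD, 6 pairs) and between genotypes 0.396 ± 0.065 (SD, 12 pairs). The difference of within minus between genotypes was 0.07 (one-sided exact permutation p = 0.057), and it was 0.089 without replicate 2 of 1398P2 (one-sided exact permutation p = 0.029). With 12N1G and N2N1G as 1 line it was 0.035, where no exact permutation p can be below 0.067. Peaks per line differed by -1165 (RPR2 minus Nfibf/f, exact permutation p = 0.886). The difference was 4499 without replicate 1 of 1398P2, 3398 without replicate 1 of all lines, 344 without line 1399M4 and 2271 without line 1399P1.

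**Figure D4:**
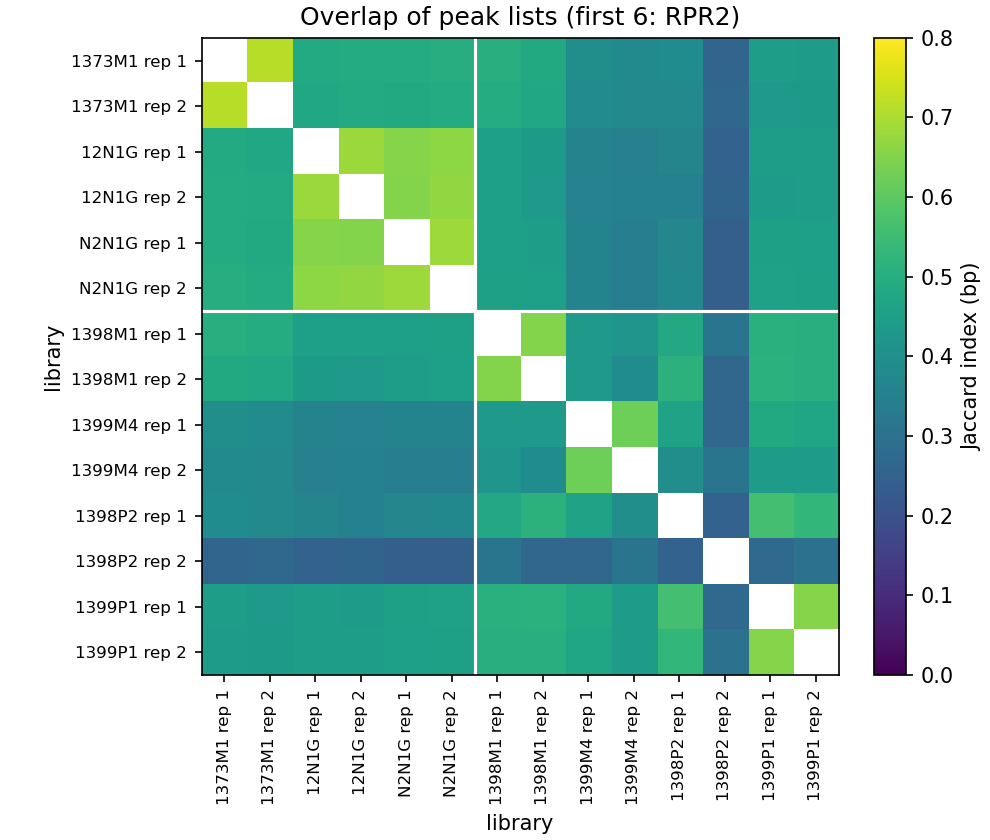
Jaccard index in bp (color) between the peak lists of the 14 libraries (both axes), with RPR2 libraries above and left of the white lines. The diagonal is left blank. Replicate 2 of 1398P2 overlaps with the other libraries at 0.2412 to 0.31, and 12N1G and N2N1G overlap like replicates.

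Among liver metastases, the tissue with both genotypes, regions open in 1373M1 and closed in both Nfibf/f lines lay most often at Gse1 and Magi1, with 17 each. Tenm2, a teneurin of synapses, had 16, and Adamtsl1 and Grik3 had 15 each. Regions open in both Nfibf/f lines alone were most frequent at Fat3, an atypical cadherin, with 9, and Stard13 with 8, followed by Aff3, Cobl and Rreb1 with 7. The highest-ranked regions lay within Dtwd2 for 1373M1 (chromosome 18, 49706990 to 49707400) and 71728 bp from Kcnh8 for Nfibf/f (chromosome 17, 52530154 to 52530981). In all, 9373 regions were open in 1373M1 alone, a number between those open in 1398M1 alone, 7806, and in 1399M4 alone, 15079. The 2 Nfibf/f lines shared 4550 regions closed in 1373M1, against 1928 and 7794 for the other pairs. With 1 line against 2, no test applies.

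Within the Nfibf/f lines, regions open in both liver metastases and closed in both lung tumors were most frequent at Ppt1 with 10, Cap1 with 7 and Trit1 with 5. These are neighbors of Mycl within the stretch of raised background. Ptprm, a receptor phosphatase, had 4 and Aopep 3. Lung tumor regions lay at Ankrd44, Chn1, Ntrk2, a neurotrophin receptor, Pax8 and Pdxdc1, with 2 each. The highest-ranked regions lay within Det1 for liver metastases (chromosome 7, 78826621 to 78827809) and within M1ap for lung tumors (chromosome 6, 82952063 to 82952835). There were 785 liver metastasis regions, of which 81 lay in 1 Mb bins of raised background, and 444 lung tumor regions. Their sum of 1229 was the lowest of the 3 splits, below 1693 for lines numbered 1398 against 1399 and 1584 for the other pairing. Without replicate 2 of 1398P2 the lung tumor regions numbered 2483, and the sum of 3279 lay between 3317 and 2738. With equal numbers of peaks per library the sum was the highest of the 3, at 1151 against 1024 and 678, as it was without replicate 2 of all lines, at 8303 against 7141 and 6116. If a peak in 1 library sufficed it ranked second, at 8370 against 8434 and 7279. Liver metastasis regions numbered 1353 without replicate 1 of 1398M1 and 1248 without replicate 1 of 1398P2.

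Within the RPR2 lines, regions open in both lymph node lines and closed in 1373M1 were most frequent at Csmd2 with 23 and Agbl4 with 22, followed by Cobl and Pde10a with 17 and Epb41l3 with 16. Regions open in 1373M1 alone gathered at Macf1 and Tenm2 with 20 each, then Nrxn3, a neurexin of synapses, and Skap1 with 19 and Dlgap2 with 18. Macf1 lies beside Mycl in the run of raised background of 1373M1, at 28.7 and 34.3 times the floor. The highest-ranked regions lay within Ifi207 for lymph node lines (chromosome 1, 173728923 to 173729444) and 38417 bp from Crem for 1373M1 (chromosome 18, 3227427 to 3227937). In all, 10915 regions were open in the lymph node lines alone and 10460 in 1373M1 alone, against 736 and 615 for the other pairs. With 2 lines against 1, no test applies.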

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

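All tests of explanations in this part were chosen only after the result was seen, except that of equally dense bins reaching 3 times the floor, which was written beforehand. Single libraries stood apart from the others of their genotype in number of peaks, by a gap that is large for the range of the group. Replicate 2 of 1373M1 had 65009 peaks, against 70286 to 72440 in the other RPR2 libraries. Replicate 2 of 1398P2 had 33558, against 67745 to 84220 in the other Nfibf/f libraries. The replicates of 1398P2 overlapped with a Jaccard index of 0.25, against 0.624 to 0.713 in the other lines, while its replicate 1 overlapped with the 2 libraries of 1399P1 at 0.562 and 0.531. Of 30 groups of values tested, 3 stood apart, and chance alone gives about 1 in 20. Outside the chromosomes analysed, 18 to 33 summits per library lay on the mitochondrial sequence.

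In Nfib, 3 regions had a peak in all RPR2 libraries and in no Nfibf/f library. Lower depth of the Nfibf/f libraries is argued against, since the deepest of them had 1.134 background fragments per bp against 0.803 in the deepest RPR2 library. A single deletion of all 3 regions is argued against as well, since 4 of 4 Nfibf/f lines had a region open in both libraries between the outermost of them. A deletion of the 2 regions nearest the promoter end stays open: peaks of Nfibf/f libraries were absent over 6652 bp around them, and peak lists cannot tell deleted from closed DNA. Lower activity of the locus in Nfibf/f lines was not tested.

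The genotype gave more specific regions and more called genes than other splits of the lines. Other splits as large were 1 of 35 in each case, the real one included, with 2209 regions against at most 1406 and 100 genes against at most 3, yet only 15 splits keep the nearly alike lines 12N1G and N2N1G together, and 1 of 15 leaves chance open for both. For regions, the short list of replicate 2 of 1398P2 matters as well: without it the genotype gave 3037 regions and another split 3042. Whether the number of called genes rests on 12N1G and N2N1G being nearly alike and counted as 2 stays open. Averaging them into 1 left 2 genes. Averaging 1398M1 and 1399P1, the next most alike pair (Jaccard index 0.5061), left 1, and averaging 1373M1 with either lymph node line left 77 and 87. Less alike Nfibf/f pairs went both ways: 1398P2 with 1399P1 (0.4163) left 27, while 1398M1 with 1399M4 (0.4168) gave 152. Pairs that share a number left 62 (1398M1 and 1398P2) and 45 (1399M4 and 1399P1), and 1399M4 with 1398P2 left 46. With the lymph node pair as 1 the log2 differences stayed at a median of 0.98 times while the median SE rose from 0.161 to 0.192. The former is largely built in for genes called on these same lines. Tissue in place of genotype cannot be told apart, since 1373M1 had 9373 regions of its own among the liver metastases, between the numbers of the Nfibf/f lines.

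Local background was raised over Nfia in 1399P1 (chromosome 4, 95.2 to 98.3 Mb) and at Mycl in 5 lines. Under the test written beforehand, crowding of peaks was not excluded: 3.72% to 100% of equally dense 100 kb bins elsewhere reached 3 times the floor, where under 5% in each library would have excluded it and the 100% rests on 3 bins. A stricter test by line, devised after that outcome, asked which such bins reach the level of the run itself: at most 0.55% at Nfia and, at Mycl, 0.91% in 1398M1 and 0.81% in 1373M1 argue against crowding there (upper exact 95% limits under 5%), while 0% of 31 and 10 bins in N2N1G and up to 40% of 5 bins in 1399M4 are too few to tell. Copy gain is consistent with ends of the runs that differed by at most 100 kb between the 2 libraries of a line, a test that crowding could also pass. A gain at Mycl that goes with metastasis stays open: an unbroken run lay over Mycl in 4 of 5 metastasis and 0 of 2 lung tumor lines (Fisher's exact p = 0.143), the background at Mycl itself gave an exact permutation p of 0.048, and the locus was picked from these data, in which all RPR2 lines are metastases.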

How the results depend on the processing

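The number of settings differed by result, with 34 for the genotype-specific regions, the main one included. Leaving out raised-background bins, requiring 50% cover and joining the lymph node lines were chosen only after seeing the data. Where no cause is named, the cause was not tested. Among comparisons, 84 of the values under settings that kept all libraries were within their tolerance, 42 moved and 2 changed sign. When libraries or lines were left out, 210 stayed, 57 moved, 4 changed sign and 2 became significant. Many of those that stayed could not have changed. Leaving out a RPR2 library or line cannot move the tissue counts of the Nfibf/f lines. Lymph node and lung tumor lines play no part in the comparison of liver lines. Counts of specific regions can only stay or rise when a library or line is left out, since fewer conditions then apply. No gene list passed adjustment in any setting, which says little of stability: passing needs at least 8 of the 13 lists at the smallest exact p of 0.0286, and with a line less no p can be under 0.05. Depth limits the absence of peaks, above all in replicate 2 of 1398P2. The 3 results on NFI motifs were not run, equal numbers of peaks give no value for peaks per line, and the overlap of 50% of the smaller interval equals the 1 bp rule by construction.

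The difference in peaks per line was 1621 at -log10 q of at least 5 and 1640 at 10, and -6829 to 4499 when leaving out libraries or lines. That in overlap was 0.034 to 0.105, with a one-sided exact permutation p of 0.029 at 0.091 without replicate 2 of all lines. RPR2-specific regions numbered 3124 if a peak in 1 library sufficed and 2889 if 1 was allowed in closed lines, as these looser rules admit more, and 1447 to 5533 when leaving out. Nfibf/f-specific regions numbered 447 at q 5, 146 at q 10, 486 with equal peaks, 231 with 50% cover, 3725 and 1249 under the looser rules, and 764 to 2951 when leaving out.

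Liver metastasis regions of Nfibf/f lines numbered 410 at q 10, 431 with equal peaks, 3012 and 2779 under the looser rules, and 785 to 10359 when leaving out. Lung tumor regions numbered 247 at q 5, 64 at q 10, 720 with equal peaks, 212 with 50% cover, 5358 and 977 under the looser rules, and 444 to 8355 when leaving out. Among liver lines, those of RPR2 numbered 5439 with equal peaks, 16874 with 1 library sufficing, and 9373 to 19849 when leaving out. Those of Nfibf/f numbered 2062 at q 10, 1784 with equal peaks, 2719 with 50% cover, 10841 with 1 library sufficing, and 4550 to 22441 when leaving out. Lymph node regions numbered 5532 at q 10, 4843 with equal peaks, 19108 with 1 library sufficing, and 10915 to 17285 when leaving out.

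List genes with a gene end open in all libraries of 1 genotype alone numbered 0 at q 10, 2 with equal peaks, 0 on autosomes, where Dcx is not, 3 under either looser rule, and 1 to 3 when leaving out. Genes called by limma numbered 62 at q 10, 55 with equal peaks, 4 with 50% cover, 1 with a 2 kb window, 2 with the lymph node lines as 1, 269 at a mean of at least 1 region, 3 at a mean of at least 5, 24 without scaling, and 1 to 440 when leaving out. Of the 62 genes at q 10, 11 were among the 100, and of the 24 without scaling, 12 were. With the 14 libraries and the line as a random effect, 400 were called. That model takes a single correlation within lines, 0.477, for all genes and counts libraries, not lines, in its degrees of freedom. Its larger number is therefore not stronger evidence.

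Neuroendocrine genes changed sign at q 10 (-0.02), with equal peaks (-0.014) and with a 2 kb window (-0.041), and fibroblast and endothelium genes with equal peaks (-0.028). The tuft-like list was -0.057 with 50% cover, and -0.05 to 0.148 when leaving out. The NOTCH and YAP list was 0.069 with 50% cover, 0.05 in fixed windows, 0.036 with a 2 kb window, and -0.08 to 0.013 when leaving out. With a 2 kb window hepatocyte genes were -0.039 and lymphocyte and myeloid genes 0.055, and lung epithelium was -0.002 to 0.091 when leaving out. Myt1 was 0.08 at q 10 and 0.13 with equal peaks, Hes1 -0.5 to 0 and Pax5 -0.04 to 0.24 when leaving out.

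Replicate numbers did not pair lines: 2 of 21 pairs of lines had a correlation above 0.1 between their replicate differences. A replicate block cannot move the difference in peaks per line (-1165) or specific regions, since every line has 1 library of each number. With it the difference in overlap was 0.071, and limma called 342 genes beside the line as a random effect, under the same limit as that model without the block.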

Other observations

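The search for runs of raised background was chosen only after the data were seen, while the tests of gene ends were planned and the genes picked by their values. All values are reported without explanation. Beyond Nfia and Mycl, runs of at least 5 bins of 100 kb with a lowest background of at least 3 times the floor in both libraries lay on chromosome 11. In 12N1G such a run lay at 6 to 6.4 Mb where both libraries shared it, over Camk2b, Ogdh and Ddx56, at 4.1 and 4 times the floor. In N2N1G it lay at 58.8 to 59.7 Mb, over Wnt3a and Wnt9a, at 4.8 and 4.3 times the floor. The 1 Mb bin at 59 to 60 Mb was raised in 12N1G too, at 3.94 and 4.48 times the floor beside 4.7 and 4.42 in N2N1G. Both also had a run at 121.6 Mb of chromosome 4, ending at 122.7 Mb in 12N1G and 122.8 Mb in N2N1G, where a further run at 122.9 to 123.4 Mb over Mycl reached 39.2 and 35.2 times the floor. In 1398M1 and 1399M4 the run ended at 123.1 Mb, past Mycl, and in 1373M1 it spanned 122.8 to 123.8 Mb with 19 protein-coding genes. Of the raised 1 Mb bins outside such runs, that at 39 to 40 Mb of chromosome 17 was the highest. There 2 to 13 summits per library between 39.84 and 39.85 Mb had a median background of 166.3 to 838.3 times the floor in all 14 libraries, and other summits of the bin had at most 1.99 times.

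Peaks at gene ends of Ptgs1, a cyclooxygenase expressed by tuft cells, were present in 0 of 6 RPR2 and 7 of 8 Nfibf/f libraries (Fisher's exact p over lines = 0.143). Pou2f3, the factor that names the tuft-like state, had 1 of 6 and 4 of 8. Gap43, a growth cone protein, had 6 of 6 and 2 of 8 (Fisher's exact p = 0.143), and Neurod6, a neurogenic factor, 6 of 6 and 4 of 8 (Fisher's exact p = 0.143). Ptgs1, Gap43 and Neurod6 are 3 of 12 list genes at this p, of which 9 had more open lines in RPR2, among them Robo2, Notch3, Zeb2, Hopx, Cdh5, Tie1 and Tek, and 3 in Nfibf/f, with Esrp1 and Ovol1 beside Ptgs1. Over 3 and 4 lines Fisher's exact p cannot go below 0.029, so adjustment over the 148 list genes leaves no p here under 0.05 by design.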
